A study of Homo sapiens with 20 samples.

How the data were processed

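The deposited files hold RT-qPCR values of a 30-gene panel in 20 samples: MSCs of 8 donors at passage 4 and at passage 8, and 1 sample each of osteoblasts, chondrocytes, dermal fibroblasts and the embryonal carcinoma line NT2. Per the labels, cells were grown in a marrow stromal cell medium, RNA was purified on columns with DNase I treatment, and PCR ran for 40 cycles with SYBR Green on a CFX96 instrument. Of the 20 samples, 17 had 1 run and 3 had 3 runs (MSCs of donor 1 and donor 6 at passage 4 and of donor 7 at passage 8), which makes 26 runs of 90 wells, with 3 wells for each gene.

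The authors deposited the quantification cycle (Cq) of every well, which lies on a reversed log2 scale, and delta Cq values, also in log2 units, under 8 normalizations (each of ACTB, GAPDH, GUSB, NACAD and ST13 alone and 3 combinations of them). The deposited delta Cq values equal the median Cq over wells minus the reference, with the geometric mean of the Cq of combined references and the median over repeat runs, to within 5e-09. The authors also deposited signed fold changes between the passages, and a table with, for each gene and normalization, a score for the slope of delta Cq on each of 5 proliferation measures, the correlation coefficient and its p-value. The measures are, per the file headers, the fraction of EdU-positive cells after 6 and 10 hours, the confluency fraction after 5 and 6 days and the population doubling time in hours. How the threshold cycle was set, which wells had been removed and which test gave the deposited p-value are not stated. A column of cutoff slopes is not explained in the file and was not used.

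The level of a gene was the mean Cq of the 5 reference genes minus the Cq of the gene, each averaged over wells and then over runs, so that repeat runs counted as 1 sample. Wells without a Cq or at 38 cycles or more were left out. CYP2B6 is marked as a housekeeping gene in the files, but 50 of its 78 wells gave no Cq, so it was not used as a reference. UBE2S lacked a usable well in 3 MSC samples. A difference of 1 cycle was taken as 2-fold, and PCR efficiencies are not given. The 30 symbols were looked up in the human gene table of assembly GRCh38.p14, where 29 matched a current symbol and SGOL2 matched a synonym. No batch or run date is given in the labels, so no relation could be recomputed within batches.

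No table of proliferation values per sample was used here. The values were solved from the deposited slopes over the 16 MSC samples: with 219 slopes for each measure and 16 samples, the values are determined up to a constant, and the deposited correlation coefficients over 16 samples then followed to within 1e-09. Only differences between samples are therefore used. The deposited coefficients over 20 samples differed from those of the solved values by up to 0.0105 and were not used. In a search over all pairs of samples, all 219 coefficients of each of the 5 measures matched to within 1e-09 only when the variance of delta Cq was taken about a mean in which 1 of the osteoblast and chondrocyte values stood in place of the other.

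Passage 8 was compared with passage 4 in limma 3.58.1 (R 4.3.3; lmFit and eBayes, two-sided) with donor as a block, since the titles name the same donor line at both passages, and with Benjamini-Hochberg adjustment over 24 target genes at a threshold of 0.05. Beside it stand the exact sign-flip test over the 256 sign patterns of 8 donors, and fry for the mitosis and spindle list. The 9 gene lists (mitosis and spindle, S phase and DNA replication or repair, CDK inhibitors and senescence-associated, stromal cell markers, osteoblast, chondrocyte and adipocyte markers, pluripotency markers, blood and endothelial markers, reference genes, plate controls) were fixed before the values were seen, and only 2 of them held target genes. Proliferation measures and reference genes were compared with the exact sign-flip test. Correlations are Pearson's r and Spearman's rho with two-sided permutation p, exact over 40320 orders for 8 samples and from 100000 permutations for 13 or more, adjusted within each family of 24 genes, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The permutations over 13 or more samples treat the samples as independent, although most MSC samples are pairs from the same donor. Figures were drawn with matplotlib 3.10.9.

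Genes were named by a rule set before the values were seen: any target gene with a value in all 16 MSC samples can be named, full statistics are given for the 10 with the smallest adjusted p, correlations for the 5 with the largest and the 5 with the smallest absolute pooled r per measure, and for each other cell type the 5 genes farthest above and the 5 farthest below the MSC mean. UBE2S, which lacks values, and the genes of the 3 samples that stood apart were singled out after their values were seen. The alternatives were no donor block, the exact test in place of limma, each reference alone, the mean of all target genes as the reference, each normalization of the authors, no normalization, undetected wells at 40 cycles, only the 22 genes with a mean Cq under 30, only run 1, medians over wells and leaving out each donor in turn. For the correlations they were other references, Spearman's rho, leaving out the 2 samples farthest from the median, subtracting passage means, adding the 4 other cell types and leaving out each donor.

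The passage comparison was tested on simulated data in 200 simulations of 23 genes with the observed spread between donors: 2.7% of genes with no simulated change were called, 8.3% of genes with a fall of 0.5 on the log2 scale, 41.7% with a fall of 1, 76.9% with a fall of 2 and 89.8% with a fall of 3. The residuals were drawn from a normal distribution independently for each gene, whereas the real genes moved together. These rates therefore do not cover calls that come in blocks. The precision of a level is limited by the wells, whose SD had a median of 0.0717 cycles in MSCs, and by the runs.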

Results

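Expression of 30 genes was measured by SYBR Green RT-qPCR in cultured human cells. The series holds 20 samples. Multipotent stromal cells (MSCs), adherent cells that can be expanded in culture and driven toward bone, cartilage or fat, came from 8 donors, each sampled at passage 4 and again at passage 8, which gives 16 samples in 8 pairs. Osteoblasts, chondrocytes and dermal fibroblasts at passage 4 and the embryonal carcinoma line NT2 gave 1 sample each. The panel held 24 target genes and 6 genes marked as housekeeping, in 3 wells each, and the study's title states that it sought genes that predict MSC proliferation. Wells of the MSC samples had a median SD of 0.0717 cycles over 616 triplicates. Levels are log2 values relative to the mean quantification cycle (Cq) of 5 reference genes, so that 1 unit is taken as a 2-fold difference and a higher value is more RNA.

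The first question was how far proliferation itself differed between the passages, since the series was designed around it. MSCs at passage 8 took up less EdU, a thymidine analogue that marks cells in S phase, than the same donors at passage 4. The EdU-positive fraction after 6 hours fell by 0.333 (SD 0.207, n = 8 pairs) and that after 10 hours fell by 0.420 (SD 0.232, n = 8 pairs). The share of the dish covered by cells fell by 0.195 (SD 0.0847) after 5 days and fell by 0.306 (SD 0.111) after 6 days, and the population doubling time rose by 27.9 hours (SD 15.0). All 8 donors moved in the same direction in each of the 5 measures. The exact two-sided sign-flip test gave p = 0.0078 for each measure (adjusted p = 0.0078 over 5 measures), which is the smallest p that 8 pairs allow. The donors differed in size, with a change in doubling time from 2.33 to 47.1 hours. Only differences between samples could be recovered from the deposited tables, so the absolute fractions and doubling times are not known. Of the 8 passage 8 samples, 5 shared the longest doubling time, and whether that value is an upper limit is not stated. If it is, the mean rise, its SD, the range over donors and the correlations with doubling time depend on that limit.

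**Figure D1:**
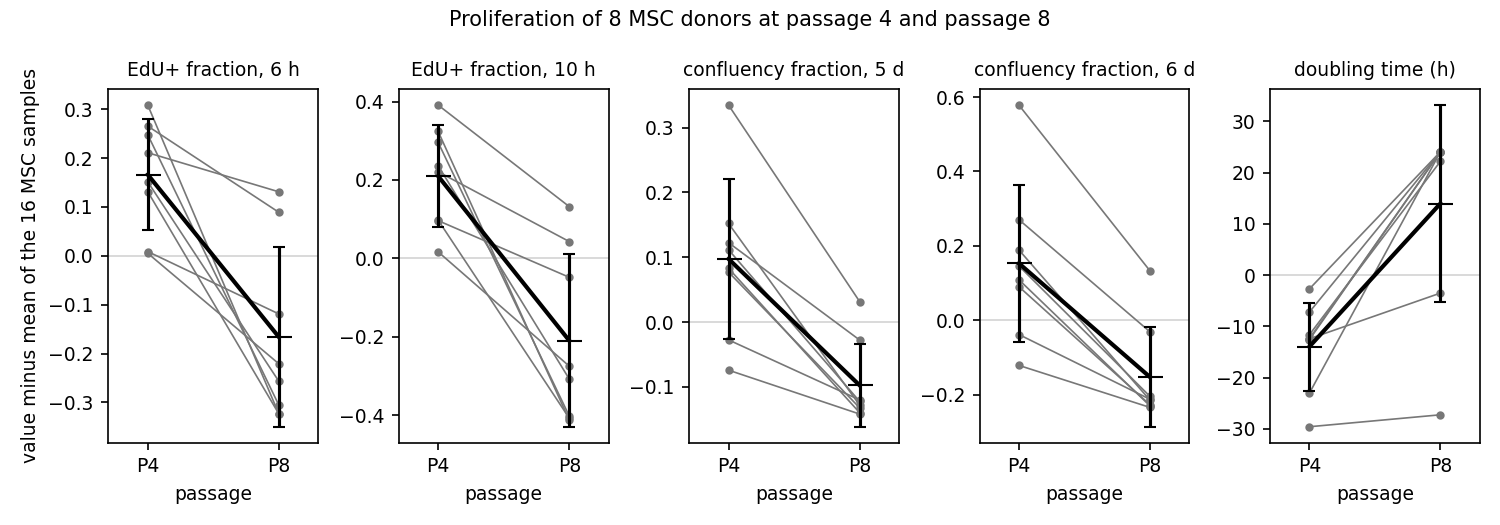
Proliferation measures of 8 MSC donors at passage 4 and passage 8, each panel in its own unit (fraction of cells, fraction of the dish, hours) as the value minus the mean of the 16 MSC samples; thin lines join the samples of a donor, and the thick line and bars are the mean ± SD. All 8 donors had lower EdU and confluency fractions and a longer doubling time at passage 8.

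The main comparison asked which panel genes differed between passage 8 and passage 4. Transcripts of the mitotic machinery fell at passage 8 while CDKN1A, which encodes the CDK inhibitor p21, rose in 8 of 8 donors by 1.36 on the log2 scale (SD 0.557, n = 8; 2.57-fold; limma adjusted p = 0.00717). CCNA2, the S and G2 phase cyclin A2, fell by 2.84 (SD 1.89), PLK1, a kinase needed for spindle assembly and mitotic exit, fell by 3.12 (SD 2.22), and CDC20, an activator of the anaphase-promoting complex, fell by 3.27 (SD 2.40), each with n = 8 and an adjusted p of 0.00717 in limma. PBK, a mitotic kinase, fell by 3.30 (SD 2.55), KIF20B, a kinesin of cytokinesis, fell by 2.08 (SD 1.56), BIRC5, the chromosomal passenger protein survivin, fell by 3.52 (SD 2.88), and CENPF, a kinetochore protein, fell by 1.91 (SD 1.48), each with n = 8 and an adjusted p of 0.00792 in limma. These falls amounted to levels 7.15-fold higher at passage 4 for CCNA2, 8.69-fold for PLK1, 9.63-fold for CDC20 and 11.4-fold for BIRC5. HAS2, a hyaluronan synthase, fell by 1.66 (SD 0.976, n = 8, adjusted p = 0.00717 in limma) in 8 of 8 donors.

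Across the panel, 19 of 24 target genes passed an adjusted p of 0.05 in limma with donor as a block, 18 lower and 1 higher at passage 8. Of the 16 measured members of the mitosis and spindle list, 15 fell and 1 did not pass, and 15 also passed when adjusted over the list alone. The study chose the panel, and the labels do not say on which samples, so the count is not independent evidence of its direction. The median fall of the 15 was 4.23-fold. As a set the 16 genes were lower (fry p = 0.00286, and exact sign-flip p = 0.0156 for their mean over 8 donors), with fry p = 0.00211 for change in either direction. CDK1, the kinase that starts mitosis, fell by 3.95 and SPC25, a subunit of the kinetochore complex NDC80, fell by 4.48. SPC25 had a Cq of 35.2, 33.3 and 36.7 in the passage 8 samples of donors 2, 3 and 8, near the cutoff of 38. Over all samples 2 of its 78 wells lay at 38 or more and were left out, so the size of its fall is uncertain. Smaller falls were seen in TPX2 (-1.40, a spindle assembly factor), KIF23 (-1.35, a kinesin of the central spindle), CKS2 (-1.31, a CDK subunit), SGOL2 (-1.24, a protector of centromere cohesion), SMC4 (-1.03, a condensin subunit) and CKS1B (-1.01, a CDK subunit). The calls of SMC4 and CKS1B, and that of FABP5 given below, ended when donor 6 was left out. KPNA2, an importin, had a difference of -0.52 (adjusted p = 0.153 in limma) and was the list member that did not pass. CDKN1A was the only measured member of the list of CDK inhibitors and senescence-associated genes, and the lists of S phase genes, stromal, lineage, pluripotency, and blood and endothelial markers had 0 measured members.

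Of the 7 target genes in no list, 3 fell. IQGAP3, a scaffold protein, fell by 3.54 (SD 2.98, n = 8, adjusted p = 0.00792 in limma), and FABP5, a fatty acid binding protein, fell by 0.93 (adjusted p = 0.0251 in limma), beside HAS2. IQGAP3 had a Cq of 34.5, 33.9 and 35.7 in the passage 8 samples of donors 2, 3 and 8, so the size of its fall is also uncertain. The other 4 did not pass: HMGB3 had a difference of -0.63 (adjusted p = 0.103), the proteoglycan gene SPOCK1 0.65 (adjusted p = 0.153), the keratin gene KRT18 0.39 (adjusted p = 0.457) and UBE2S -0.48 (adjusted p = 0.575, limma). Without donor 8, whose differences in HMGB3, SPOCK1 and KRT18 had the other sign, these 3 passed in limma, with -0.78 (adjusted p = 0.0417), 0.98 (adjusted p = 0.0140) and 0.81 (adjusted p = 0.0465). The Cq of single references rose by 0.247 (ST13) to 3.75 cycles (NACAD) in donor 8. The sign of its HMGB3 and SPOCK1 differences therefore depends on the reference. UBE2S had a value in 13 of 16 samples and 6 pairs. The exact sign-flip test over donors, adjusted over 24 genes, also passed 19 genes, with adjusted p from 0.0288 to 0.0395. With NACAD as the sole reference the count was 12 and the calls of CKS1B, CKS2, FABP5, KIF23, SGOL2, SMC4 and TPX2 ended. With the mean of all target genes as the reference the count was 12, of which 8 were lower and 4 higher, and the estimates of CKS1B, CKS2, FABP5, HAS2, HMGB3, KIF23, KPNA2, SGOL2, SMC4, TPX2 and UBE2S turned positive. CENPF (-0.14, adjusted p = 0.769 in limma) and KIF20B (-0.31, adjusted p = 0.562 in limma) also did not pass with this reference. It removes by construction any change shared by the panel, so genes that fall less than the panel mean turn positive.

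**Figure D2:**
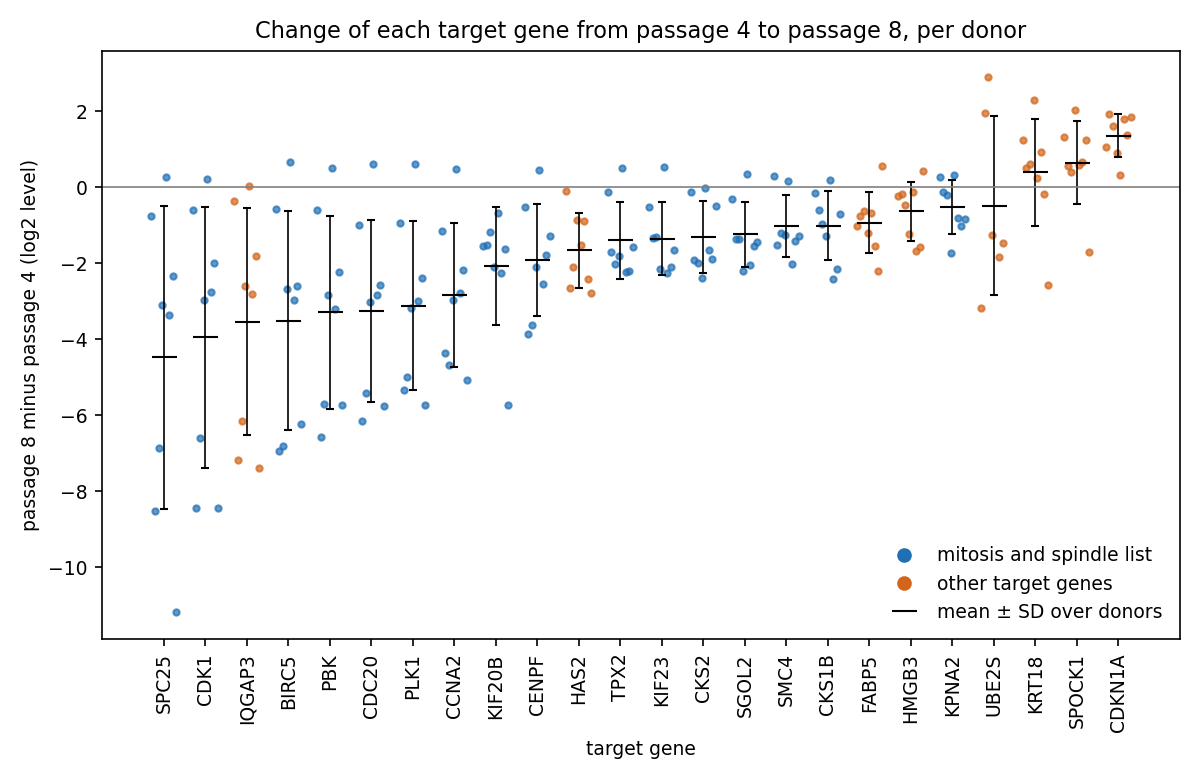
Difference in log2 level, passage 8 minus passage 4, of the 24 target genes on the horizontal axis, relative to 5 reference genes; points are donors and black bars the mean ± SD over donors. The means run from -4.48 for SPC25 to 1.36 for CDKN1A, and with the mean of all target genes as the reference 11 of the genes with a mean below 0 turn positive. That reference removes by construction any change shared by the panel.

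The donors differed in how far the mitotic genes fell. The mean difference of the 16 mitosis and spindle genes was -2.27 (SD 1.53, n = 8, exact sign-flip p = 0.0156), and it ran from -3.95 in donor 8, -3.77 in donor 2 and -3.43 in donor 3 to -0.52 in donor 1 and 0.32 in donor 5. The place of donor 8 among these depends on the reference, as the Cq of its references rose by 0.247 (ST13) to 3.75 cycles (NACAD). In donor 5 only 2 of the 16 genes had a lower value at passage 8, against 14 in donor 1 and 16 in each of the other 6 donors. The passage 8 samples of donors 2, 3 and 8 stood apart from the other 13 MSC samples. In these 3 samples the mean level of BIRC5, CCNA2, CDC20, CDK1, PBK, PLK1 and SPC25 lay between -9.63 and -9.06, while the other 13 samples lay between -4.82 and -1.22. The same 3 samples had the lowest EdU fractions of the 16 after 6 hours and after 10 hours. Those of donors 3 and 8 shared the lowest 6-hour value, and whether that value is a lower limit is not stated. Without donors 2, 3 and 8, a comparison chosen after the values were seen, 20 genes passed in limma, 18 of them shared with the 19 above, but the falls were smaller: CDK1 fell by 1.62, SPC25 fell by 1.85, BIRC5 fell by 1.63, CDC20 fell by 1.76 and PLK1 fell by 1.78. The set test no longer passed in these 5 donors (fry p = 0.0645, and exact sign-flip p = 0.125 for the mean of the 16 genes, -1.40, where 0.0625 is the smallest p that 5 donors can give).

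The reference genes themselves were compared between passages on their Cq. Cq was higher at passage 8 for GUSB, a lysosomal glucuronidase, by 0.921 cycles (SD 0.997, n = 8, exact sign-flip p = 0.0156, adjusted p = 0.0521), for NACAD by 0.980 (exact p = 0.0313, adjusted p = 0.0521) and for ACTB by 0.529 (exact p = 0.0313, adjusted p = 0.0521). GAPDH had a difference of 0.434 cycles (exact p = 0.0703, adjusted p = 0.0879) and ST13, a co-chaperone of HSP70, 0.0336 cycles (exact p = 0.789, adjusted p = 0.789). None of the 5 passed after adjustment. The mean of the 5 was higher in 8 of 8 donors, by 0.580 cycles (SD 0.678, exact p = 0.0078, the smallest that 8 pairs allow), and by 0.375 cycles without donor 8 (exact p = 0.0156, a comparison chosen after the values were seen). The p without donor 8 was fixed in advance, because all 8 donors moved in the same direction.

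The next comparison asked which genes followed proliferation over the MSC samples. CDKN1A was higher in samples that incorporated less EdU: its r with the 10-hour EdU fraction was -0.87 over 16 samples (permutation p = 3e-05, adjusted p = 0.00072 over 24 genes; rho = -0.83, permutation p = 0.00013), and -0.80 without the 2 samples farthest from the median. CDC20 (r = 0.80), PLK1 (r = 0.80), BIRC5 (r = 0.79) and IQGAP3 (r = 0.78) were higher in samples with more EdU, each with an adjusted permutation p of 0.00096. CDC20 had rho = 0.74 (permutation p = 0.00139) and r = 0.68 without the 2 farthest samples. With the 6-hour fraction the largest r values were CDKN1A -0.80, BIRC5 0.74, CDC20 0.74, PLK1 0.74 and IQGAP3 0.73, each with an adjusted permutation p of 0.00319. With doubling time they were CDKN1A 0.81, PLK1 -0.74, IQGAP3 -0.74, CCNA2 -0.74 and CDC20 -0.73. With confluency after 5 days they were CDKN1A -0.72, CCNA2 0.65, PLK1 0.64, IQGAP3 0.64 and BIRC5 0.63, and after 6 days CDKN1A -0.73, IQGAP3 0.64, PLK1 0.64, CCNA2 0.63 and CDC20 0.63.

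Leaving out UBE2S, which had a value in 13 of the 16 samples, genes with r near 0 included SPOCK1, with 0.071 for the 6-hour EdU fraction, 0.020 for the 10-hour fraction and 0.045 for doubling time, and KRT18, with 0.16, 0.17 and 0.011. HMGB3 had r = 0.17 and 0.28 with the 6-hour and 10-hour EdU fractions, HAS2 0.18 and 0.29, and KPNA2 0.28 and 0.39. With confluency after 5 and 6 days the smallest were KRT18 (-0.086 and -0.025), SPOCK1 (-0.22 and -0.13), HAS2 (0.32 and 0.24), FABP5 (0.41 and 0.44) and KPNA2 (0.42 and 0.44), and with doubling time HAS2 had -0.24, HMGB3 -0.42 and FABP5 -0.45.

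Over the 16 samples, 9 of 24 genes passed an adjusted permutation p of 0.05 with the 6-hour EdU fraction, 13 with the 10-hour fraction, 6 with each confluency measure and 15 with doubling time, in 5 families of 24 tests. These 16 samples are 8 donors at 2 passages and, as described, 3 of them stood apart, so the pooled values mix differences between passages, between donors and between these 3 samples and the rest. Without the 2 samples farthest from the median no gene passed for the 6-hour EdU fraction or either confluency measure, while 9 genes passed for the 10-hour fraction and 10 for doubling time. For doubling time the 5 passage 8 samples with the longest value were equally far from the median. Which 2 of them were left out was therefore arbitrary, and the count of 10 depends on that pick. Without the 2 farthest samples of each measure CDKN1A had r = -0.71 (from -0.80) and BIRC5 0.59 (from 0.74) with the 6-hour fraction, and CCNA2 had r = 0.63 (from 0.65) and 0.67 (from 0.63) with confluency after 5 and 6 days. In the 13 samples without the 3 that stood apart, a comparison chosen after the values were seen, 0 of 24 genes passed for any measure (1, 1, 5, 3 and 7 genes at an unadjusted permutation p under 0.05, in the order 6-hour EdU, 10-hour EdU, confluency at 5 and 6 days, doubling time). There CDKN1A had r = -0.72 with the 10-hour EdU fraction (adjusted permutation p = 0.123) and CDC20 r = 0.49 (adjusted permutation p = 0.425). The confluency counts also depended on single donors: without donor 6 they were 18 and 16, and without each other donor in turn they were 0, except 6 for the 5-day measure without donor 1. Subtracting each passage's mean also left 0 genes past the adjusted threshold for each measure, with 3, 9, 0, 0 and 3 genes at an unadjusted p under 0.05 in the same order. With the 10-hour fraction CDKN1A then had r = -0.70 (adjusted permutation p = 0.0730) and CDC20 r = 0.60 (adjusted permutation p = 0.0781).

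Within 1 passage, and over the 8 donor differences, 0 of 24 genes passed an adjusted exact permutation p of 0.05 for Pearson's r with any of the 5 measures. At an unadjusted exact permutation p under 0.05, 4 genes passed at passage 4 and 9 at passage 8 for the 6-hour EdU fraction, 10 at passage 8 for the 10-hour fraction, and 0 in the other 12 families. Spearman's rho passed for 11 genes with the 6-hour and 6 genes with the 10-hour EdU fraction at passage 8, and for 0 genes elsewhere. At passage 8, CDKN1A had r = -0.88 with the 6-hour fraction (n = 8, exact permutation p = 0.00422, adjusted p = 0.0875) and r = -0.90 with the 10-hour fraction (n = 8, exact permutation p = 0.00285, adjusted p = 0.0685), and CDC20 had r = 0.76 and 0.80. At passage 4, CDC20 had r = -0.66 and -0.24 and CDKN1A r = 0.20 and -0.23 with the same fractions.

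**Figure D3:**
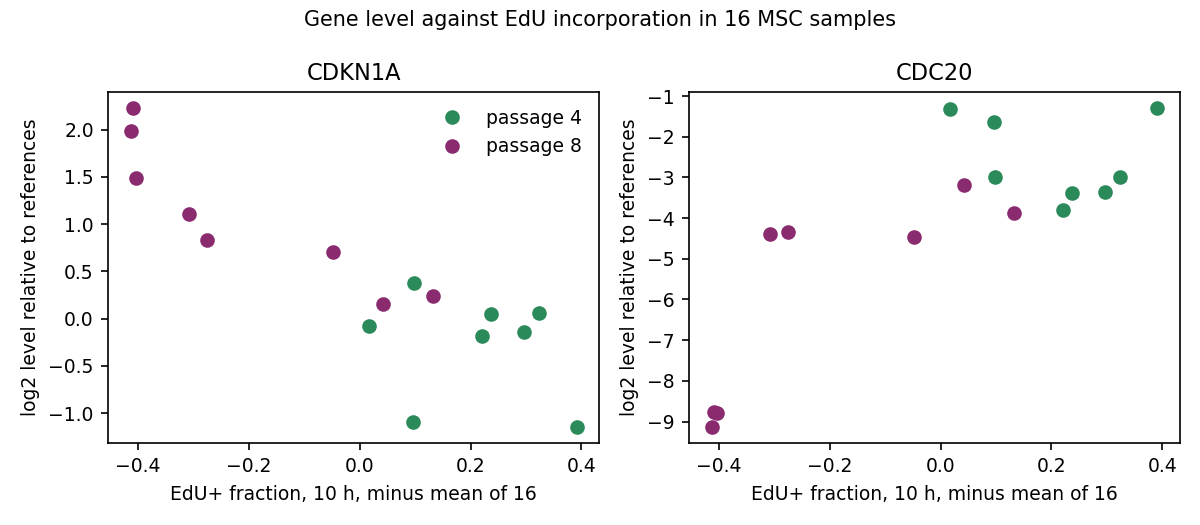
Log2 level of CDKN1A (left) and CDC20 (right) relative to the reference genes against the EdU-positive fraction after 10 hours, minus the mean of the 16 MSC samples; each point is 1 sample, coloured by passage. Pooled r was -0.87 for CDKN1A and 0.80 for CDC20, and the 3 passage 8 samples with the lowest EdU fraction lie apart in CDC20; without them r was -0.72 and 0.49.

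The 4 other cell types were set beside the 8 MSC samples at passage 4, with 1 sample each and therefore no test. The embryonal carcinoma line NT2 lay above the range of the 8 MSC samples in 15 of 24 target genes, below it in 3 and within it in 6. UBE2S, with a value in 7 of the 8 MSC samples, is counted among the 24 genes for each cell type but is left out of the highest and lowest differences given here, as the rule for naming genes required a value in every MSC sample. The largest differences of NT2 above the MSC mean were CENPF (3.40 higher on the log2 scale), CKS1B (2.79), SPC25 (2.43), PLK1 (2.28) and CKS2 (2.26), all members of the mitosis list. NT2 lay below the MSC range in HAS2 (-6.19), CDKN1A (-4.43) and SPOCK1 (-2.58), and the next lowest differences, leaving out UBE2S, were those of PBK (0.33) and IQGAP3 (0.34). The chondrocyte and dermal fibroblast samples lay within the MSC range in 24 of 24 genes each. These levels depend on the references, some of which lay outside the MSC range relative to their own mean. In chondrocytes ACTB lay below it (difference from the MSC mean -1.06) and ST13 (0.59) and NACAD (0.38) above it. GAPDH lay below it in dermal fibroblasts (-0.53), and GAPDH (0.58) and ST13 (0.43) lay above it in NT2. The other references lay within it in these samples. In chondrocytes the highest differences from the MSC mean were SPOCK1 (0.66), KIF20B (0.23), FABP5 (0.09), SMC4 (0.05) and HMGB3 (-0.04), and the lowest were IQGAP3 (-1.22), TPX2 (-0.94), HAS2 (-0.78), CCNA2 (-0.77) and PLK1 (-0.74). In dermal fibroblasts the highest were HAS2 (0.73), BIRC5 (0.24), KIF20B (0.19), CDKN1A (0.15) and KPNA2 (0.02), and the lowest were KRT18 (-2.06), FABP5 (-0.74), SPOCK1 (-0.59), KIF23 (-0.47) and CKS2 (-0.45).

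The osteoblast sample lay outside the MSC range in 19 of 24 genes, 13 above and 6 below, but its wells disagreed. Its median SD over 3 wells was 0.756 cycles, against 0.0717 in MSCs, 14 of its 22 triplicates exceeded an SD of 0.5, and 11 of 87 wells in 7 genes gave no Cq. The wells of the 5 reference genes had SDs of 1.55 (ACTB), 1.75 (GAPDH), 1.61 (GUSB), 3.60 (NACAD) and 2.60 cycles (ST13), and every level of this sample depends on their mean. Leaving out UBE2S again, its highest differences from the MSC mean were SPOCK1 (3.49), KRT18 (3.11), KIF23 (3.01), KPNA2 (2.81) and PLK1 (2.57). Its lowest were CDKN1A (-7.81) and CCNA2 (-5.88), each from 1 well, CKS2 (-4.71, 2 wells), CKS1B (-4.55, 1 well) and BIRC5 (-3.66), whose 3 wells ran from 24.5 to 34.7 cycles.

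For 3 MSC samples the labels give 3 replicates each, read here as repeat runs, and whether they repeat the assay, the RNA or the culture is not stated. The median SD over runs of the 24 target genes was 0.145, against a median SD of 1.01 over the 8 donors at passage 4. It lay between 0.0685 and 0.246 for 21 genes and was 0.380 for KIF20B, 0.518 for IQGAP3 and 2.72 for UBE2S. KIF20B and IQGAP3 were lower in run 3 than in run 1 in each of the 3 samples. For IQGAP3 the level went from -5.41 to -5.82 in donor 1, from -4.11 to -5.39 in donor 6 and from -4.83 to -5.73 in donor 7. The other 17 samples had 1 run, so averaging over runs lowered these 2 genes in the repeated samples only.

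The authors also deposited fold changes between the passages and correlations with proliferation. The sign of their fold change with all 5 references combined was the same as here in 24 of 24 genes, and the largest gap in size was 0.47 on the log2 scale, for SPC25. Wells at 38 cycles or more entered the authors' delta Cq but were left out here. Their r values are for delta Cq, which falls as the level rises, so their sign runs the other way. For BIRC5 with the 6-hour EdU fraction they gave -0.743, against 0.738 here. With the sign turned and the same references, their r values over 16 samples differed from those here by at most 0.0658, leaving out UBE2S. The proliferation values here were solved from the authors' own slopes, so this closeness is no independent check of the correlations. In their table, 13 genes had an unadjusted p under 0.05 with the 6-hour EdU fraction, 15 with the 10-hour fraction, 17 and 14 with confluency after 5 and 6 days and 17 with doubling time.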

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

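The tests of chance, of PCR efficiency, of less RNA and of a chance difference between the passages were chosen or framed only after the result each measures was seen. Of 102 groups of 8 or fewer values that were searched for a value far from the rest of its group, 6 held one, and about 5.1 are expected by chance. Of these 6, 5 belonged to donor 8.

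ACTB had a Cq of 17.9 in the passage 4 sample of donor 5, with the other 7 samples between 16.5 and 17.0. GUSB had a Cq of 24.2 in the passage 4 sample of donor 8, against 25.0 to 25.7 in the others. KIF20B had a level of -13.14 in the passage 8 sample of donor 8, against -9.61 to -7.73 in the others, and its difference between passages in this donor was -5.73, against -2.27 to -0.69. Its Cq in that sample was 36.0, near the cutoff of 38. KRT18 had a level of -2.54 in the same sample, against 0.81 to 2.79 in the other passage 8 samples. SPOCK1 changed by -1.69 in donor 8, against 0.41 to 2.05 in the other 7 donors. CYP2B6, a cytochrome P450 gene that no comparison uses, gave a mean Cq of 32.4 in chondrocytes and 29.9 in embryonal carcinoma cells, below the 36.7 to 40.9 cycles of the 19 of 66 MSC wells that gave a Cq.

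The number of genes that differed between the passages was tested by swapping the passage labels within donors. The real labels gave 19 genes, and in 100 label patterns, the real one included, 1 gave as many, with a highest other count of 18. The pattern that gave 18 differed from the real one by the swap of 1 donor. No other pattern drawn gave as many genes, which argues against chance as the whole account of the count. The genes moved together, however, so the count is not built from independent calls. The labels do not say on which samples the panel was chosen, and label swaps cannot test that choice. Chance together with the choice of the panel therefore cannot be excluded.

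The size of the fall differed among mitosis genes. BIRC5, CCNA2, CDC20, CDK1, PBK, PLK1 and SPC25 had falls from -2.84 to -4.48, while CENPF, CKS1B, CKS2, KIF23, KPNA2, SGOL2, SMC4 and TPX2 had differences from -0.52 to -1.91, a division made after the values were seen. A lower PCR efficiency of the second set is argued against, because it would flatten differences between donors as well as between passages: the slope of these genes on the first set was 0.870 (median) over the passage 4 samples and 0.171 over the donor differences, a median ratio of 5.47 with a lowest ratio of 2.24. A candidate explanation is a constant amount of template that remains when the rest falls. A constant added to the falling amount predicted left-out donors better than a straight line in 7 of 8 genes, all but CENPF. The median error was 0.469 against 0.722 on the log2 scale. The straight line was the only rival, and the slope over the passage 8 samples (median 0.144) was already lower than over the passage 4 samples. The low end of the first set rests on the 3 samples that stood apart. Any curve that flattens could therefore do better than the line, so the comparison cannot single out a constant amount. Whether such an amount exists, as transcript present outside mitosis or as an off-target product, stays open. No control without reverse transcription was analysed here.

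The 5 reference genes moved apart between the passages in donor 8, where the Cq of ST13 rose by 0.247 cycles from passage 4 to passage 8, GAPDH by 1.25, ACTB by 1.83, GUSB by 3.00 and NACAD by 3.75. The range of these changes was 3.502 cycles, against 0.780 to 1.64 in the other 7 donors, which argues against less RNA as the whole account, because less RNA moves all references by the same number of cycles. Disagreement among wells of the passage 8 sample is argued against as well, since the median SD over wells of the references there was 0.1154 cycles, against 0.1153 in the MSC samples. The passage 4 sample of donor 8 had the lowest passage 4 Cq for GUSB (24.2), NACAD (25.9) and ST13 (21.4). Part of the changes may therefore lie in that sample. A change of the reference transcripts themselves in these cells, and damage to the RNA that differs between transcripts, stay open, and no biological explanation was tested. Without donor 8, 22 genes passed in the passage comparison, so the count does not rest on this donor.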

How the results depend on the processing

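The lists, tests, reference and alternatives were chosen before the data were examined, except the comparisons without donors 2, 3 and 8 or their passage 8 samples, without the 3 genes that shift between repeat runs, the gene list test under the authors' normalizations and single donors left out, the leave-one-out values of the reference genes, the counts of Spearman's rho and of 2 samples left out within a passage or over donor differences, and the well handling of the other cell types, which were chosen after seeing the data. For the proliferation measures, alternatives on a time course were not run, since the tables used here hold no time course. At the residual spread seen over 8 donors, genes that fall by 1 were called in 41.7% of simulated tests, and other spreads, other numbers of donors or genes that move together were not simulated.

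The count of genes differing between passages was 19. It was 17 with no replicate block, where FABP5 and HAS2 no longer passed, and 16 to 22 when 1 donor was left out, the lowest without donor 6 (CKS1B, FABP5 and SMC4 no longer passed) and the highest without donor 8 (HMGB3, KRT18 and SPOCK1 passed). It was 12 with NACAD alone, 12 with the authors' NACAD normalization and 12 with the mean of all target genes as the reference, and between 17 and 21 with the other references, normalizations and filters. BIRC5, CCNA2, CDC20, CDK1, CDKN1A, PBK, PLK1 and SPC25 passed under every alternative run, and IQGAP3 under each that tested it. The reference moves the median difference of all genes from -1.37 to 0.39 with the mean of all target genes, where 9 of 16 mitosis genes stayed below 0 and 7 passed as lower; that reference removes by construction any change shared by the panel. With it the differences turned to 0.76 for CKS1B, 0.46 for CKS2, 0.84 for FABP5, 0.10 for HAS2, 1.14 for HMGB3, 0.42 for KIF23, 1.25 for KPNA2 (adjusted p = 0.0267), 0.53 for SGOL2, 0.74 for SMC4, 0.37 for TPX2 and 1.36 for UBE2S. KRT18 turned to -0.16 with ST13 alone, -0.11 with the authors' ST13 normalization and -0.19 with Cq as deposited, and the causes were not tested. UBE2S lay between -1.16 and 0.053 when 1 donor was left out. The set test of the mitosis list gave p from 0.000479 to 0.00926 under the alternatives, except 0.0645 without donors 2, 3 and 8, where 5 donors remain.

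The falls in proliferation kept their direction and their side of the threshold with no replicate block (exact permutation p from 0.00109 to 0.00404). They also did so without each donor, which was fixed in advance because all 8 donors moved in the same direction in each measure. When 1 donor was left out, the change in Cq ran from 0.343 to 0.620 for ACTB, 0.318 to 0.518 for GAPDH, 0.585 to 1.14 for NACAD and -0.0359 to 0.102 for ST13, and from 0.375 to 0.649 for the mean of all 5 references. The count of genes outside the MSC range was 16 with medians over wells and 21 with undetected wells at 40 cycles for osteoblasts (19 in the report), and did not move for the other 3 cell types.

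The counts of genes correlated with proliferation over 16 samples depended on the reference and on the samples. For 6-hour EdU (9) the count was 15 with ACTB alone, 20 with ST13 alone, 16 with the mean of all target genes, and 0 with the 2 farthest samples left out, with passage means subtracted, or without the passage 8 samples of donors 2, 3 and 8. For 10-hour EdU (13) it was 20 with ST13 alone, 0 with passage means subtracted and 0 without those 3 samples. For 5-day confluency (6) it was 11 with ACTB alone, 0 with NACAD alone, 20 with ST13 alone, 13 with Spearman's rho, 0 to 18 when 1 donor was left out, and 0 with 2 samples left out, passage means subtracted or those 3 samples left out. For 6-day confluency (6) it was 15 with ACTB alone, 1 with GAPDH alone, 0 with NACAD alone, 19 with ST13 alone, 0 with the mean of all target genes, 10 with Spearman's rho, 0 to 16 when 1 donor was left out, and 0 under the same 3 choices of samples. For doubling time (15) it was 9 with NACAD alone, 0 with passage means subtracted and 0 without those 3 samples. Within passage 8, Spearman's rho passed for 11 genes with 6-hour EdU and 6 genes with 10-hour EdU, where Pearson's r passed for 0. The causes were not tested.

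The sign of r turned only in SPOCK1, KRT18, HMGB3, HAS2, KPNA2 and FABP5, among the genes named for each measure. With the mean of all target genes as the reference, r turned to SPOCK1 -0.52, KRT18 -0.35, HMGB3 -0.72, HAS2 -0.34, KPNA2 -0.76 for 6-hour EdU and SPOCK1 -0.61, KRT18 -0.40, HMGB3 -0.74, HAS2 -0.27, KPNA2 -0.78 for 10-hour EdU. It turned to HAS2 -0.13, FABP5 -0.31, KPNA2 -0.57 for 5-day confluency and HAS2 -0.22, FABP5 -0.28, KPNA2 -0.55 for 6-day confluency. It turned to HAS2 0.30, HMGB3 0.62, FABP5 0.37 for doubling time. With NACAD alone, r turned to SPOCK1 -0.35, KRT18 -0.12, HMGB3 -0.29, HAS2 -0.0074, KPNA2 -0.24 for 6-hour EdU and SPOCK1 -0.40, KRT18 -0.11, HMGB3 -0.21, KPNA2 -0.13 for 10-hour EdU. It turned to HMGB3 0.046 for doubling time. With ST13 alone, r turned to KRT18 0.060, SPOCK1 0.014 for 5-day confluency and KRT18 0.10, SPOCK1 0.071 for 6-day confluency. It turned to KRT18 -0.15, SPOCK1 -0.20 for doubling time. With ACTB alone, r turned to KRT18 0.046 for 6-day confluency and KRT18 -0.086, SPOCK1 -0.090 for doubling time. With GUSB alone, r turned to SPOCK1 -0.15, HMGB3 -0.19, KPNA2 -0.053 for 6-hour EdU and SPOCK1 -0.19, HMGB3 -0.049 for 10-hour EdU. With GAPDH alone, r turned to KRT18 0.027 for 6-day confluency and KRT18 -0.058, SPOCK1 -0.055 for doubling time. With Spearman's rho, r turned to SPOCK1 -0.012 for 6-hour EdU and SPOCK1 -0.11, KRT18 -0.026 for 10-hour EdU. With the 2 farthest samples left out, r turned to SPOCK1 -0.29, KRT18 -0.055, HAS2 -0.082 for 6-hour EdU and SPOCK1 -0.24, KRT18 -0.16 for 10-hour EdU. It turned to KRT18 -0.14, SPOCK1 -0.094 for doubling time, where the 2 samples were an arbitrary pick among 5 equally far ones. With passage means subtracted, r turned to HMGB3 -0.42, HAS2 -0.26, KPNA2 -0.045 for 6-hour EdU and HMGB3 -0.25, HAS2 -0.11 for 10-hour EdU. It turned to KRT18 0.025, SPOCK1 0.056, HAS2 -0.014 for 5-day confluency and KRT18 0.098, SPOCK1 0.16, HAS2 -0.10 for 6-day confluency. It turned to KRT18 -0.13, SPOCK1 -0.31, HAS2 0.12 for doubling time. With the 4 other cell types added, r turned to SPOCK1 -0.039 for 6-hour EdU and KRT18 -0.019 for doubling time. With the passage 8 samples of donors 2, 3 and 8 left out, r turned to SPOCK1 -0.26, KRT18 -0.066, HAS2 -0.20, KPNA2 -0.012 for 6-hour EdU and SPOCK1 -0.37, KRT18 -0.072, HAS2 -0.045 for 10-hour EdU. It turned to HAS2 0.022 for doubling time. When 1 donor was left out, SPOCK1 ran from -0.18 to 0.16 for 6-hour EdU, -0.27 to 0.12 for 10-hour EdU and -0.074 to 0.30 for doubling time. KRT18 ran from -0.093 to 0.25 for 6-hour EdU, -0.12 to 0.25 for 10-hour EdU, -0.37 to 0.039 for 5-day confluency, -0.29 to 0.11 for 6-day confluency and -0.093 to 0.32 for doubling time. The mean of all target genes removes by construction any relation with proliferation shared by the panel, so genes with a weaker relation can turn sign with it. The causes of the other turns were not tested.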

Other observations

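The test of a chance difference between the passages was framed only after its result was seen. The r of the mean level of the 16 mitosis and spindle genes with the EdU fraction had opposite signs at the 2 passages. At passage 4 its r with the 6-hour EdU fraction was -0.71 (n = 8, exact permutation p = 0.0561) and at passage 8 it was 0.75 (n = 8, exact permutation p = 0.0314). With the 10-hour fraction it was -0.39 (n = 8, exact permutation p = 0.327) and 0.77 (n = 8, exact permutation p = 0.0235). Swapping the passages within donors, after centring each passage, gave a difference between the correlations as large in a share of 0.03125 of the within-donor swaps (exact), and 0.0156 for the 10-hour fraction, but 0.0781 for both after adjustment over the 5 measures, so that a chance difference cannot be told apart from a real one with 8 donors. That 1 donor carries the negative value at passage 4 is argued against for the 6-hour fraction, where r without 1 donor ran from -0.885 to -0.591, but not for the 10-hour fraction, where it ran from -0.863 to -0.102, the weakest without donor 4. Without the 2 samples farthest from the median the passage 4 r was -0.43 with the 6-hour and -0.76 with the 10-hour fraction. The difference between the passages therefore stays open.

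The proliferation measures followed each other over the 16 MSC samples, so the 5 families of correlations are not independent of each other. These pooled relations include the difference between passages that all donors shared. At passage 4 alone the absolute r between 2 measures ran from 0.38 (6-hour EdU with 5-day confluency) to 0.98 (the 2 confluency measures). The mean level of the 16 mitosis genes had r = 0.68 with the 6-hour EdU fraction, 0.75 with the 10-hour fraction, 0.62 and 0.61 with confluency after 5 and 6 days and -0.71 with doubling time over the 16 samples. In the 13 samples other than the passage 8 samples of donors 2, 3 and 8, the same r was 0.24 (permutation p = 0.422), 0.36 (permutation p = 0.224), 0.49 (permutation p = 0.0878), 0.46 (permutation p = 0.116) and -0.51 (permutation p = 0.0706), in the same order. Over the 8 donor differences the change in these genes had r = 0.53 (exact permutation p = 0.18) with the change in the 6-hour EdU fraction, 0.54 (exact p = 0.172) with the 10-hour fraction and -0.49 (exact p = 0.208) with doubling time. With confluency after 5 and 6 days the sign was the other way from the pooled values, at -0.22 (exact permutation p = 0.602) and -0.33 (exact p = 0.435), and none of the 5 passed.

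The samples of a donor were paired by their titles. The deviations of a donor's 23 gene levels from the mean of each passage correlated across genes, which are not independent replicates, between 0.0471 and 0.620. The 2 most similar samples differed by 0.405 on the log2 scale (root mean square), so no 2 samples held the same values.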
